A study of Mus musculus with 49 samples.

How the data were processed

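Messenger RNA was sequenced from 43 libraries and open chromatin (ATAC-seq) from 6, all from C57BL/6 mouse cells. The groups, with replicate numbers, came from the sample titles and tags: BMDM of each genotype at 0, 4 and 16 h of LPS (3 libraries each), naive CD4 T cells labelled KO (4) with WT (3), naive CD4 T cells with W250S (3) and WT (3), Th17 cells of each genotype in each culture (3 each), and KO and WT naive CD4 cells for ATAC-seq (3 each). Samples whose titles name WT together with W250S carry the genotype WT and were taken as the WT of that set. Every column of values was mapped to a sample.

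Per the submitters' processing notes, the genome build was mm10 and the tools were BWA, MACS2, Partek 10.0.21.0411, Bowtie2 and DESeq2, with no statement of which tool served which assay. The RNA tables hold CPM computed by the authors, as their headers and names state. In the macrophage and the KO naive table the lowest value is 0.0001, as if that amount had been added throughout. The deposited CPM sum to 950599 to 954161 per BMDM library, to 472848 to 494423 in the KO naive table, and to 489990 to 543838 in the W250S tables, so the scaling covers more than the genes listed. The unit step between small values gives the reads behind a library: 11.0 to 15.9 M in BMDM, 23.4 to 27.1 M in the KO naive set, 24.6 to 32.3 M in the W250S naive set, 25.4 to 33.4 M in non-pathogenic and 25.9 to 37.7 M reads in pathogenic Th17 cells. The ATAC-seq table deposited by the authors holds expected counts, that is, estimated reads per peak over 1 common set of 86911 peaks, with 6.19, 6.56 and 9.71 M in peaks for WT and 13.7, 9.61 and 13.5 M for KO replicates 1, 2 and 3. The peaks' genes and positions relative to the start of the gene are the authors' annotation.

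RNA values were analysed as log2(CPM + 1) with limma 3.58.1 (lmFit, eBayes with trend) in R 4.3.3. Genes with at least 1 CPM in at least 3 libraries were tested, two-sided, and called at a Benjamini-Hochberg adjusted p below 0.05. The 18 BMDM libraries were fitted together with 1 mean per genotype and time, and each T cell table on its own. In macrophages the variance of a gene is therefore shared by all times, and a p-value does not measure the spread at 1 time alone. The fit also takes the 18 libraries as independent, with 17.3 residual degrees of freedom. Libraries of the same genotype and number varied together between times, as given below, so these degrees of freedom may be too many. An interaction is the difference of 2 such differences: the KO effect at 4 or 16 h minus that at 0 h, the KO-labelled minus the W250S effect in naive cells, fitted over both tables, and the W250S effect in pathogenic minus non-pathogenic cells, fitted to the difference between cultures of each source of cells that the labels name. ATAC-seq counts were rounded and tested with edgeR 4.0.16 (TMM, filterByExpr, glmQLFit, glmQLFTest), and with DESeq2 1.42.0 as an alternative. Duplicate gene entries with identical values were kept once (1 in the BMDM table), and gene names turned into dates by spreadsheet software (19 or 20 in each T cell table) were left out of the fits over 2 tables. The overlap and correlation of the naive effects kept them, matched as written.

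Gene lists for the cell types and treatments were fixed before the data were examined, as were the comparisons, tests, thresholds and most of the alternatives. They cover pro-inflammatory cytokines, anti-inflammatory regulators, neutrophil and other chemokines, inflammation amplifiers, inflammasome, TLR signalling, interferons and interferon-stimulated genes, antigen presentation, alternative activation, macrophage identity, lysosome, glycolysis, cholesterol synthesis, cell cycle, immediate early and heat shock genes, ETS factors, T cell states, and markers of other cell types and sex. Lists with at least 5 tested members were tested with limma's camera (preset correlation 0.01, adjusted within a comparison), and beside it with camera at an estimated correlation and with fry. Of 216 list tests 92 passed, and 23 of these held with an estimated correlation. The interferon list, with 1 tested member, the sex list, with at most 4, and the markers of T, B, CD8 and NK, erythroid, myeloid, and mast and basophil cells had too few tested members in any comparison. Counts of list members are given adjusted over all genes and adjusted over the list alone.

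The text names genes by a rule fixed in advance: key genes of the study; of called genes with a mean of at least 5 CPM and groups that do not overlap, the 10 largest changes each way; of each list, up to 4 called members and up to 2 abundant members that were not called; for interactions the 5 largest each way; and for peaks those at Elf4 and the largest changes each way. Predicted and numbered gene models were counted but not named, and a few other genes that the rule selects are left out. Groups of 3 against 3 fail to overlap by chance for 10% of unchanged genes, and 4 against 3 for 5.71%.

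Macrophage libraries carry replicate numbers in their labels. Deviations from the group means correlated between libraries of the same genotype and number for every pair of 0 h with 4 h (0.17 to 0.25 in WT, 0.19 to 0.53 in KO) and of 0 h with 16 h in WT (0.11 to 0.31), but not for every pair of 0 h with 16 h in KO (0.06 to 0.52). A fit with genotype and number as a block is therefore given beside a result where every pair varied together and the block changes a call or a count.

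Across genes, log2 fold changes were compared by Pearson and Spearman correlation with 100000 permutations, and calls by Fisher's exact test. For ATAC-seq and RNA, the tested peak of highest mean among those annotated as the start of a gene was used. The table gives no distances, so that annotation stands in for the distance planned. With few peaks called, Fisher's test took the genes called for RNA and the sign of the peak's fold change, in place of genes called in both as planned. Alternatives planned in advance were a pseudocount of 0.1, no filter on low values, at least 5 CPM, median-ratio scaling of the libraries, a fit to the compared groups alone, the replicate number as a block, and each library left out. For ATAC-seq they were DESeq2 with its size factors, no filter and an adjusted p below 0.01. Chosen after the data were seen were fits without BMDM KO replicate 2, a block of genotype and replicate number for the interactions and for the gene lists, the immediate early and heat shock list as a covariate in naive cells, a fit without naive WT replicate 3 and KO replicate 4, and the correlations without each library. Each count was also compared with those of other splits of the same libraries, at most 100.

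The procedure was tested on simulated data with known changes, at the depth of each table and with 1 typical spread for all its genes. The simulation leaves out differences in spread between genes and between groups, so recovery in the real tables may be lower. In the comparisons of mutant with WT cells, changes of 1.5-fold were recovered for 41.8 to 80.3% and of 2-fold for 85.9% or more of RNA genes. In these comparisons 5 to 16 unchanged genes were called as well, the most in pathogenic Th17 cells. For ATAC-seq peaks 10.8% of 1.5-fold and 60.0% of 2-fold changes were recovered. For the interactions, 1.5-fold changes were recovered for 15.9 to 36.4% of genes.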

Results

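RNA sequencing and ATAC-seq, a measure of open chromatin, were run on C57BL/6 mouse cells that were wild type (WT), knockout (KO) for Elf4, or carried Elf4 W250S, a single amino-acid substitution. Elf4 encodes an ETS-family transcription factor, and the series title names it as a regulator of inflammation. Bone marrow-derived macrophages (BMDM), grown for 7 days with M-CSF, were collected untreated or 4 h or 16 h after lipopolysaccharide (LPS, 100 ng/ml, a bacterial product sensed by TLR4), with 3 libraries per genotype and time. Naive CD4 T cells gave 2 RNA sets, each with its own WT libraries: 4 libraries labelled KO with 3 WT, and 3 W250S with 3 WT. W250S and WT T cells were also cultured for 48 h with IL-6, IL-23 and IL-1 beta (pathogenic Th17) or with IL-6 and TGF-beta (non-pathogenic Th17), 3 libraries per genotype and culture. ATAC-seq covered naive CD4 libraries, 3 labelled KO and 3 WT, for 49 samples in all. RNA values were CPM (read counts scaled to the depth of the library), group values are means ± SD with n = 3 unless given, and fold changes are log2 differences of log2(CPM + 1), mutant against WT. The spacing of the smallest values puts the reads behind each library at 11.0 to 15.9 M in BMDM and at 23.4 to 37.7 M in the T cell sets.

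Elf4 transcripts fell in KO macrophages at every time: the log2 fold change was -2.22 at 0 h (22 ± 3.23 against 105 ± 7.96 CPM), -1.95 at 4 h (17.2 ± 2.63 against 68.7 ± 5.07 CPM) and -2.12 at 16 h (29.5 ± 2.65 against 132 ± 2.52 CPM), each with an adjusted p of at most 1.89e-08. In naive CD4 T cells the libraries labelled KO held Elf4 at 189 ± 13.8 against 191 ± 4.87 CPM, a log2 difference of -0.014 (adjusted p = 0.932, n = 4 and 3). W250S changes the protein sequence, and its transcript did not pass the threshold in naive cells (0.17, adjusted p = 0.45), pathogenic Th17 cells (0.094, adjusted p = 0.347) or non-pathogenic Th17 cells (0.17, adjusted p = 0.114).

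**Figure D1:**
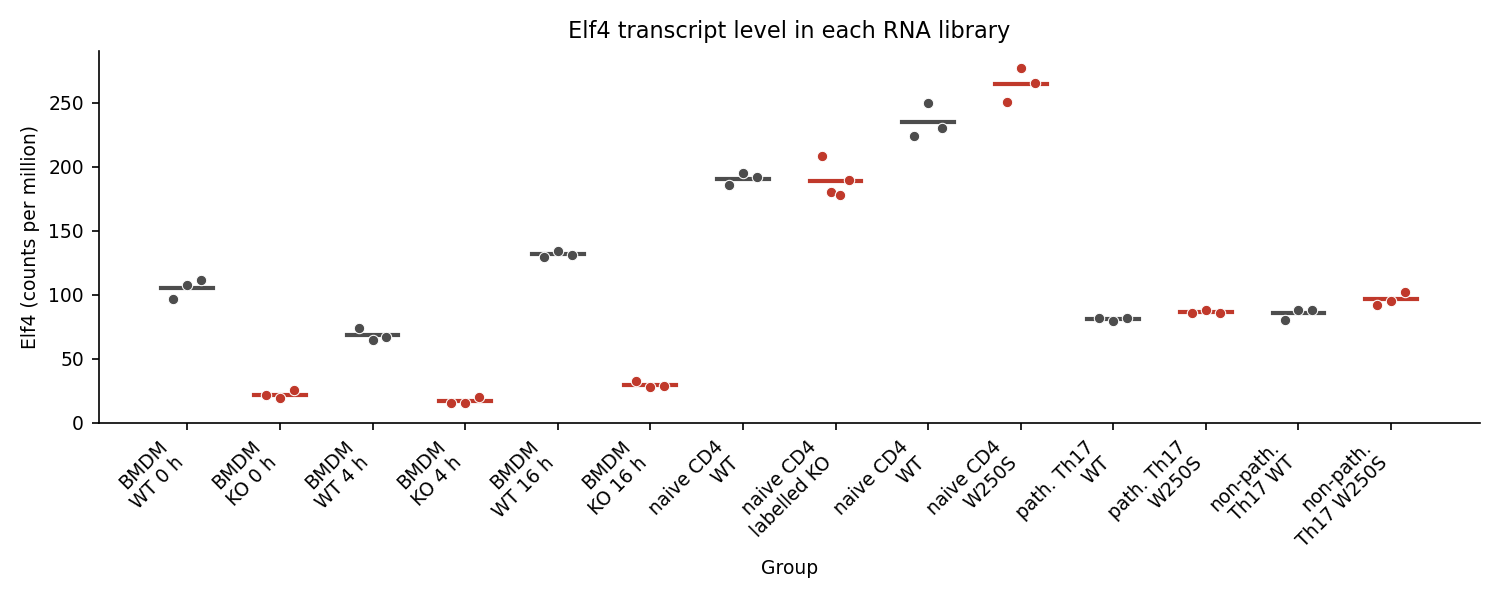
Elf4 in CPM (vertical axis, linear, from 0) in each RNA library, by group (horizontal axis); points are libraries and bars are group means. The KO macrophage groups average 22.0, 17.2 and 29.5 CPM against 105, 68.7 and 132 in WT, while the naive CD4 libraries labelled KO average 189 against 191.

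The WT time course gives the response against which the KO is read. At 4 h of LPS, WT macrophages turned on the acute inflammatory program: inducible cytokines, prostaglandin and nitric oxide enzymes, chemokines and antiviral genes rose together, and proliferation genes fell. Nos2, the inducible nitric oxide synthase, rose by 10.11 log2, the itaconate enzyme gene Acod1 by 10.12, the prostaglandin enzyme gene Ptgs2 by 9.65, and the T cell chemoattractant Cxcl10 by 9.83. Il6 rose by 9.45, Il12b by 9.44, Il1b by 9.08 and Tnf by 6.97. Restraint came up with them: Il1rn, the secreted IL-1 receptor antagonist, rose by 7.13 and Il10 by 6.94. The antiviral gene Rsad2 rose by 7.77 and Ifnb1, which encodes interferon beta, by 3.79. The myeloid transcription factor gene Cebpa fell (-6.35) and the stress-response gene Sesn1 (-6.45); every gene named here had an adjusted p of at most 4.98e-05. Of 12058 genes tested, 1876 rose and 8593 fell, with a median over all genes of -0.81 log2; after median-ratio scaling that median was -0.069, with 4029 genes up and 4719 down. Elf4 itself stood at -0.61 (adjusted p = 4.98e-05), less than the shift of all genes, and at 0.23 after that scaling.

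Of the fixed gene lists, pro-inflammatory cytokines rose, with all 18 tested members up, also adjusted over the list alone. The chemokines, neutrophil chemoattractants, inflammation amplifiers, inflammasome, anti-inflammatory, TLR signalling and dendritic cell lists rose with them, in order 16 of 17, 6 of 10, 10 of 16, 12 of 19, 23 of 28, 19 of 28 and 4 of 6 genes up, the same numbers over each list alone. These camera calls held with an estimated correlation (adjusted p of at most 0.039), and so did that on alternative activation, whose median was -0.041 while its mean, 0.77, and its test pointed up. Interferon-stimulated genes rose, 38 of 39 also over the list alone (adjusted p = 4.1e-31, and adjusted p = 0.0554 with an estimated correlation), as did antigen presentation (9 up, 2 down of 18, adjusted p = 6.34e-08, and adjusted p = 0.101 with an estimated correlation). Immediate early and heat shock genes split, 8 up and 11 down, with a median of -0.55 but a mean of 0.38 and a test pointing up (adjusted p = 0.00766, and adjusted p = 0.0622 with an estimated correlation). All 31 cell cycle genes fell (adjusted p = 0.000845, and adjusted p = 0.53 with an estimated correlation).

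In WT cells at 16 h of LPS, the iron-binding protein gene Lcn2 rose by 9.97 log2 over 0 h, the acute-phase gene Saa3 by 9.22, the arginase gene Arg1 by 7.05 and the alarmin gene S100a8 by 3.41. Il1b stood at 1892 CPM and Il1rn at 3664 CPM, while Il10 was 20.4 CPM (2.47) and Ifnb1 0.208 ± 0.0761 against 0.0478 ± 0.0416 CPM, too low at both times for this test to show a difference. The mannose receptor gene Mrc1 fell (-4.98), the prostaglandin-degrading enzyme gene Hpgd (-6.88), and the proliferation genes Ccna2 and Top2a (-5.84 and -5.48); Elf4 rose by 0.32 (adjusted p = 0.0137). In all 2203 genes rose and 6818 fell around a median of -0.41 (median-ratio scaling: -0.022, 3905 up, 4202 down). All 39 interferon-stimulated genes rose (adjusted p = 9.27e-29) and all 31 cell cycle genes fell (adjusted p = 6.13e-11). Antigen presentation (adjusted p = 3.66e-07), TLR signalling (adjusted p = 5.58e-06) and dendritic cell genes (adjusted p = 0.00514) leaned up, as did alternative activation genes (adjusted p = 0.0432) against their median of -0.09 (adjusted p = 0.091 with genotype and replicate number as a block). With an estimated correlation each of these had an adjusted p of at least 0.0603. Calls that held with an estimated correlation (adjusted p of at most 0.0449) were glycolysis (16 of 20 up, 16 over the list alone) and immediate early and heat shock (10 up, 6 down). So did the cytokine, neutrophil and other chemokine, amplifier, inflammasome and anti-inflammatory lists, all up, and cholesterol synthesis, with all 21 genes down.

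Before LPS, KO macrophages differed from WT in 53 genes, 17 up and 36 down, with fewer each way after median-ratio scaling. The protease gene Adam19 rose by 1.46 ± 0.30 (SE) log2 (15.4 ± 7.15 against 4.79 ± 1.84 CPM). Alox5, which makes leukotrienes, rose by 1.06 and the macrophage actin regulator Aif1 by 0.70. The cytokine-signal inhibitor Socs3 rose by 0.67, the formyl peptide receptor gene Fpr2 by 0.69, and Rtn1 and Sema6d by 1.14 and 1.05. The actin-binding gene Vill fell (-1.67), the glycosylation enzyme gene Galnt12 (-1.36), the phospholipase gene Plcb2 (-1.26), the glutamine transporter gene Slc1a5 (-0.82) and the glycolytic enzyme gene Pfkp (-0.52). Il1rn was 33 ± 3.95 against 21.2 ± 3.56 CPM (adjusted p = 0.102). Trem1, an amplifier of myeloid inflammation, was 12.8 ± 6.74 against 7.53 ± 1.21 CPM (adjusted p = 0.529) and S100a8 4.58 ± 4.02 against 1.95 ± 0.729 CPM (adjusted p = 0.566), so none passed. The inflammation amplifier list leaned up by a median of 0.57 log2 over 16 genes, with 1 past the threshold over all genes and 4 adjusted over the list alone (adjusted p = 7.23e-07, and adjusted p = 0.0581 with an estimated correlation). Markers of stromal cells leaned the same way (median 0.84 over 9 genes, adjusted p = 0.00013, and adjusted p = 0.456 with an estimated correlation), with Col1a1 at 353 ± 199 against 164 ± 55.5 CPM and the largest sum in KO replicate 2. Alternative activation genes (median 0.33, adjusted p = 0.00187), antigen presentation genes (0.15, adjusted p = 0.00442), neutrophil chemoattractants (0.24, adjusted p = 0.00971) and interferon-stimulated genes (0.15, adjusted p = 0.00971) leaned up. Cholesterol synthesis genes leaned down (-0.13, adjusted p = 0.00187). With an estimated correlation each of these had an adjusted p of at least 0.0754. The count of 53 moved with each library left out: 19, 18 and 19 without WT replicates 1, 2 and 3, and 83, 21 and 95 without KO replicates 1, 2 and 3. A fit to the 0 h libraries alone called 1 gene.

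At 4 h of LPS, the neutrophil chemokines Cxcl1, Cxcl2 and Cxcl3 rose in KO macrophages by 0.92, 0.64 and 0.73 log2 (Cxcl2 801 ± 51.1 against 519 ± 108 CPM), and Csf3, the granulocyte growth factor G-CSF, rose by 1.60 (20.1 ± 8.36 against 5.68 ± 1.86 CPM). Trem1 rose by 1.28 ± 0.28 (SE; 21.2 ± 3.61 against 8.21 ± 1.67 CPM, adjusted p = 0.0143). The prostaglandin E2 synthase gene Ptges rose by 1.01, Fpr2 by 0.50, Adam19 by 1.66, the plasminogen activator inhibitor gene Serpinb2 by 1.23 and the acute-phase gene Hp by 1.43. S100a8 was 8.59 ± 4.02 against 2.63 ± 1.03 CPM (adjusted p = 0.0543). Hif1a rose by 0.59, the glucose transporter gene Slc2a1 by 0.64, the lactate exporter gene Slc16a3 by 1.17 and the stress gene Ddit4 by 1.57. Irak3, a brake on TLR signalling, rose by 0.94 and the cytokine Il19 by 1.03. The anti-inflammatory regulators did not pass as a list (2 of 28 up, 4 over the list alone; adjusted p = 0.81).

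On the other side, Ifnb1 fell (-1.04 ± 0.24 SE; 6.66 ± 3.60 against 13.5 ± 1.0 CPM, adjusted p = 0.0194). Irf8, a transcription factor that drives interferon and IL-12 genes, fell (-0.83), Il12a (-0.80), and the interferon gamma-type targets Gbp4 and Cxcl9 (-1.23 and -1.02). The signalling regulator Rgs1 fell (-1.17), the T cell costimulator Tnfsf4 (OX40 ligand; -1.06), Vill (-1.31) and the inflammasome adaptor Pycard (-0.46). The classical response genes did not pass at this time. Il1b was 3465 ± 621 against 2303 ± 337.1 CPM (adjusted p = 0.201), Il6 -0.30 log2, Tnf -0.22, Nos2 -0.042, Il1rn 0.18 and Il10 0.23. The most abundant interferon targets Rsad2 and Cxcl10 stood at -0.26 and -0.074, and all these had an adjusted p of at least 0.201.

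In all 505 genes passed at 4 h, 287 up and 218 down (271 up and 323 down after median-ratio scaling). Of 10 neutrophil chemoattractants 4 rose (8 adjusted over the list alone; median 0.78, adjusted p = 1.55e-05), and of 16 inflammation amplifiers 3 rose (6 up and 1 down over the list alone; median 0.60, adjusted p = 0.0022). Of 20 glycolysis genes 4 rose and 1 fell (4 and 2 over the list alone; adjusted p = 0.0134). With an estimated correlation each of these had an adjusted p of at least 0.0519. The inflammasome list leaned down, with 1 member past the threshold (5 down and 1 up over the list alone; median -0.13, adjusted p = 0.00342, and adjusted p = 0.173 with an estimated correlation). Interferon-stimulated genes leaned down (median -0.11, adjusted p = 0.00542, and adjusted p = 0.743 with an estimated correlation), with no call among its 39 genes by limma and 0 down over the list alone. The lysosome list leaned down as well (-0.089, adjusted p = 0.035, and adjusted p = 0.6 with an estimated correlation; 1 up, 1 down). Stromal markers again leaned up (median 1.0, adjusted p = 0.00342, and adjusted p = 0.576 with an estimated correlation). The count fell to 268, 250 and 247 without WT replicates 1, 2 and 3, to 299 without KO replicate 2, and to 248 in a fit to the 4 h libraries alone.

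**Figure D2:**
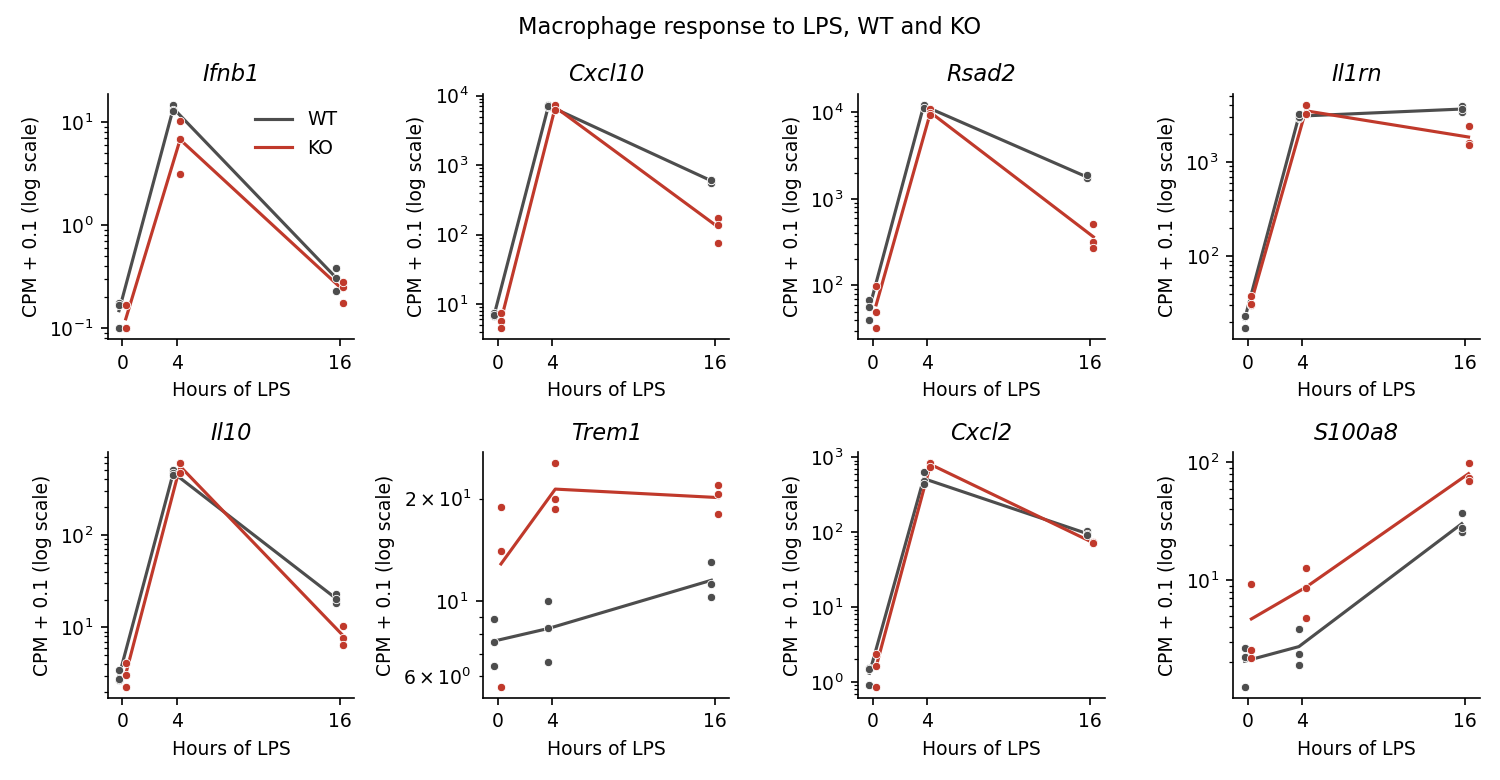
CPM (vertical axes, log scale, 0.1 added for the drawing) of 8 genes in each macrophage library against hours of LPS (horizontal axes), WT and KO; points are libraries and lines join group means. At 16 h Cxcl10 averages 128 CPM in KO against 593 in WT and Il1rn 1847 against 3664, while S100a8 averages 80.1 against 30.1.

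At 16 h the macrophage genotypes had separated widely. In KO cells the antiviral genes Rsad2 and Cmpk2 fell (-2.35 and -2.22 log2; Rsad2 365 ± 126 against 1802 ± 73.4 CPM, adjusted p = 3.77e-05), Ifit2 (-1.89), Ifit1bl1 (-3.15) and the guanylate-binding protein gene Gbp4 (-2.88). The interferon-induced T cell chemokines went with them, Cxcl11 (-3.28), Cxcl10 (-2.28 ± 0.20 SE; 128 ± 48.8 against 593 ± 31.7 CPM) and Cxcl9 (-1.34), as did the monocyte chemokine Ccl7 (-1.15) and the endothelial lipase gene Lipg (-3.11). Irf7, at 1478 ± 189.7 against 2301 ± 12.4 CPM, did not pass (adjusted p = 0.0947) in this fit, whose variance is shared by all times. Ifnb1, at 0.135 ± 0.0527 against 0.208 ± 0.0761 CPM, was too low in both genotypes for this test to show a difference. Of 39 interferon-stimulated genes 30 fell and 0 rose (32 and 0 adjusted over the list alone), with a median of -0.65 (adjusted p = 3.16e-20, and adjusted p = 0.182 with an estimated correlation). With fry, which passed 77 of 216 list tests against 23 with an estimated correlation, the adjusted p was 0.0064.

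Among genes that restrain inflammation, at 16 h Il1rn fell (-1.02; 1847 ± 496 against 3664 ± 258 CPM, adjusted p = 0.000216), Il10 (-1.25; 8.06 ± 2.04 against 20.4 ± 2.42 CPM) and the IL-18 binding protein gene Il18bp (-1.16). Of 28 anti-inflammatory regulators 13 fell and 3 rose, with the same numbers over the list alone (adjusted p = 3.02e-05, and adjusted p = 0.105 with an estimated correlation). Among the effectors, Nos2 fell (-1.13), Il12b (-1.05), Il15 (-1.05), Il1a (-0.97), Il6 (-0.75) and Tnf (-0.71). In all 9 of 18 pro-inflammatory cytokines fell (9 over the list alone; adjusted p = 3.02e-05, and adjusted p = 0.105 with an estimated correlation). Il1b stood apart at 2443 ± 136 against 1892 ± 36 CPM, with groups that did not overlap (2347 to 2598 in KO, 1856 to 1928 in WT). It did not pass (adjusted p = 0.251), but that p rests on a variance taken over all macrophage libraries. It therefore does not measure the spread at 16 h. Of 19 inflammasome genes 11 fell (12 over the list alone), among them the caspase gene Casp4 (-0.70) and Il18 (-0.68); this call held with an estimated correlation (adjusted p = 8.07e-06 and 0.0405). Among genes of antigen display, the costimulators Cd86 and Cd40 were down (-1.20 and -0.87), the peptide transporter gene Tap1 (-0.69), and 9 of 18 list members (9 over the list alone; adjusted p = 3.02e-05, and adjusted p = 0.251 with an estimated correlation). Of 17 other chemokines 9 fell and 1 rose, alike over the list alone (adjusted p = 8.07e-06, and adjusted p = 0.105 with an estimated correlation). The double-stranded RNA sensor gene Tlr3 fell (-1.08) while the lipoprotein sensor gene Tlr2 rose by 0.86. There were 11 down and 2 up of 28 TLR signalling genes (11 and 3 over the list alone; adjusted p = 0.000107, and adjusted p = 0.182 with an estimated correlation).

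Proliferation, cholesterol and glycolysis genes leaned the other way, as did single myeloid genes. S100a8 rose by 1.38 (80.1 ± 16 against 30.1 ± 6.06 CPM), Trem1 by 0.76, the matrix protease gene Mmp9 by 1.35 and Cxcl3 by 0.53, while Cxcl2 (-0.41), Lcn2 (0.18) and Saa3 (0.51) did not pass. Nor did the neutrophil chemoattractant list (2 of 10 up, 2 over the list alone; adjusted p = 0.508). The genes F13a1, Tmem119 and Mrc1 rose by 2.96, 1.80 and 0.63, Adam19 by 1.65 and the lysozyme gene Lyz2 by 0.77. Of 31 cell cycle genes 20 rose and 1 fell (23 and 1 over the list alone; adjusted p = 4.62e-05, and adjusted p = 0.477 with an estimated correlation), among them Top2a, Ccna2 and Bub1, up by 1.38, 1.38 and 1.38. The cholesterol enzyme gene Sqle rose by 1.0, and 11 of 21 genes of its list rose (11 over the list alone; adjusted p = 0.000128, and adjusted p = 0.105 with an estimated correlation). The metabolic regulator genes Pdk1 and Hif1a rose by 0.81 and 0.64 with 13 of 20 glycolysis genes up and 2 down (14 and 2 over the list alone; adjusted p = 0.000611, and adjusted p = 0.272 with an estimated correlation). The chaperone gene Hspa1a fell (-1.49), with 6 immediate early and heat shock genes down and 1 up of 20 (7 and 1 over the list alone; adjusted p = 0.000156, and adjusted p = 0.0566 with an estimated correlation). The macrophage identity, ETS factor and granulocyte lists did not pass (medians 0.12, 0.055 and 0.68, adjusted p of at least 0.539), here or in any other comparison. The lysosome list leaned down (-0.12, adjusted p = 0.0236, and adjusted p = 0.477 with an estimated correlation). Stromal genes were higher in the same libraries: Col3a1 rose by 1.57 (186 ± 132 against 54.6 ± 15.8 CPM) and Acta2 by 1.32. The stromal markers summed to 2834 CPM in KO replicate 2, 1426 and 899 CPM in KO replicates 1 and 3, and 526 to 968 CPM in WT.

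In all 3683 of 12058 genes passed at 16 h, 2520 up and 1163 down, around a median of 0.12 log2. After median-ratio scaling the median was 0.037, with 1669 genes up and 1619 down. Without KO replicate 2 at every time, a choice made after its stromal values were seen, 2963 genes passed. Replicates differed more within KO than within WT at 16 h. Squared differences between them averaged 12.8 to 31.1 times sampling noise in KO and 4.8 to 5.68 times in WT. The fit gives both genotypes 1 variance per gene.

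Whether the KO effect itself changed with LPS was tested as the difference of the differences. At 16 h the KO effect differed from that at 0 h for 778 genes, 437 with a positive and 341 with a negative difference (201 and 404 after median-ratio scaling). Among the largest negative differences were those at the interferon-inducible genes Ifit1bl1 (-3.36), Gbp4 (-3.15), Cxcl11 (-3.12) and Iigp1 (-2.51) and at Lipg (-3.14), and among the largest positive ones those at the replication gene Pclaf (1.73), Plpp5 (1.53), Ccna2 (1.44) and Draxin (1.44). Differences also passed for Il1rn (-1.64), Il10 (-1.30), Nos2 (-1.26), Il1a (-1.05), Il15 (-1.66), Cd86 (-1.78) and Rsad2 (-2.35). Of 39 interferon-stimulated genes 17 had a negative difference past the threshold (30 over the list alone; median -0.87, adjusted p = 3.67e-27, and adjusted p = 0.0865 with an estimated correlation). The calls on cholesterol synthesis (median 0.47, 10 up of 21), other chemokines (-0.78, 4 down of 17), pro-inflammatory cytokines (-0.57, 3 down of 18) and the inflammasome (-0.29, 4 down of 19) held with an estimated correlation (adjusted p of at most 0.0408). The count was 282 and 412 without WT 0 h replicates 2 and 3, 438 without KO 0 h replicate 3, 333, 439 and 311 without WT 16 h replicates 1, 2 and 3, and 334 without KO 16 h replicate 2.

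At 4 h the difference from 0 h passed for 1 gene, the microtubule-associated tumor suppressor gene Mtus1 (-1.17, adjusted p = 0.0153), with 874 genes at an unadjusted p under 0.05 where 603 would be expected. Ifnb1 stood at -1.0 (adjusted p = 0.383), so its fall at 4 h is not shown to differ from 0 h. Libraries of the same genotype and replicate number varied together between 0 h and 4 h. With genotype and number as a block, chosen after the count of 1 was seen, 43 genes passed, 26 with a positive and 17 with a negative difference, and Ifnb1 still did not. As groups, interferon-stimulated genes leaned negative (median -0.26, adjusted p = 1.35e-06, and adjusted p = 0.547 with an estimated correlation) and neutrophil chemoattractants positive (0.52, adjusted p = 0.0165, and adjusted p = 0.349 with an estimated correlation). Other chemokines passed only with the block (adjusted p = 0.0245, and 0.0924 without it). The count was 0 without WT 0 h replicate 2 or 3 or WT 4 h replicate 3, 2 without KO 0 h replicate 1 or 2, WT 4 h replicate 2 or KO 4 h replicate 3, 6 without KO 0 h replicate 3, 3 without KO 4 h replicate 2 and 40 without KO 4 h replicate 1.

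**Figure D3:**
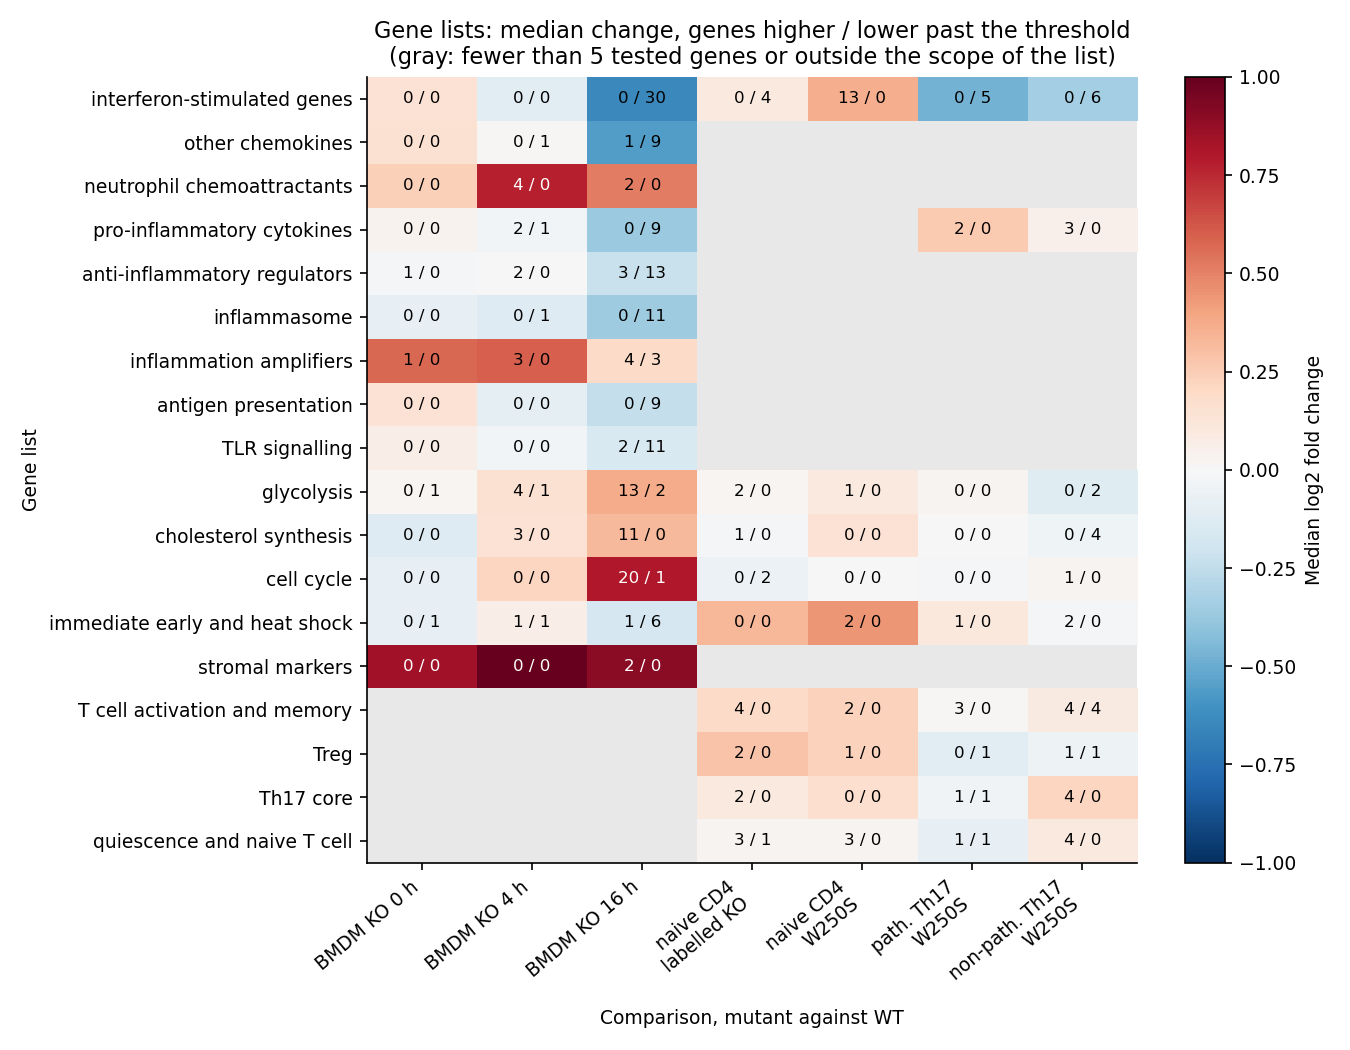
Median log2 fold change (color) of fixed gene lists in each mutant comparison, with the number of members past the threshold, higher and lower, written in each cell; rows are lists and columns are comparisons. Interferon-stimulated genes have medians of -0.65 in BMDM KO at 16 h, 0.36 in naive W250S, -0.47 in pathogenic and -0.34 in non-pathogenic W250S Th17 cells.

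Naive CD4 T cells were compared without stimulation, to ask which resting-state genes change with Elf4. In the libraries labelled KO the prostacyclin receptor gene Ptgir rose by 1.79 ± 0.099 (SE; 16.7 ± 1.85 against 4.11 ± 0.354 CPM, adjusted p = 7.53e-06, n = 4 and 3). The creatine kinase gene Ckb rose by 1.56, the receptor-sorting gene Gprasp2 by 1.49, the lubricin gene Prg4 by 1.49, the potassium channel gene Kcna2 by 1.47 and the proteoglycan gene Gpc1 by 1.38. Cd1d1, which presents lipids to NKT cells, fell (-1.38; 6.12 ± 0.729 against 17.5 ± 1.44 CPM), Ifit1bl1 (-1.30), the steroid enzyme gene Hsd17b11 (-1.17), the p38-family kinase gene Mapk11 (-1.15), the oxidase subunit gene Ncf4 (-1.13) and Prr13 (-1.11). The antiviral genes Oas2 and Oas1a fell (-1.01 and -1.04). Single genes of T cell states rose: Cd44 by 0.34 (adjusted p = 0.041), Il2rb by 0.55, Ly6c1 by 0.37, Ctla4 by 0.66, Gpr83 by 0.79, Stat4 by 0.51 and Tgfb3 by 0.91. Of the quiescence and naive T cell list, Dapl1 rose by 0.85, Igfbp4 by 0.58 and the transcription factor gene Lef1 by 0.37, while Slfn2 fell (-0.30; adjusted p = 0.0396). The list did not pass (3 up and 1 down of 30, 3 and 3 over the list alone; adjusted p = 0.411). Its other regulators named here did not pass, with Klf4 at 8.18 ± 5.61 against 1.99 ± 1.47 CPM (adjusted p = 0.214), Klf2 at 0.12 log2, S1pr1 at 0.13 and Il7r at -0.052.

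In all 1036 of 12904 genes passed, 566 up and 470 down. T cell activation and memory genes leaned up, with 4 of 21 past the threshold (6 adjusted over the list alone; adjusted p = 0.00311). So did Treg genes (2 of 9, 4 over the list alone; adjusted p = 0.0125) and Th1 and Th2 genes (2 of 6, 3 over the list alone; adjusted p = 0.0295). The pathogenic Th17 signature leaned up with Stat4 and Tgfb3 called (2 of 5, 2 over the list alone; adjusted p = 0.0161). With an estimated correlation each of these had an adjusted p of at least 0.262. Interferon-stimulated genes did not move as a group (median 0.10, adjusted p = 0.733), with 4 of 34 down, also over the list alone. Markers of other cells did not move alike in the same libraries. Of the immunoglobulin genes, made by B cells, the most abundant, Ighm, was 181 ± 18.2 against 186 ± 3.06 CPM (adjusted p = 0.774), while Igkc rose by 2.10 (5.80 ± 3.40 against 0.448 ± 0.661 CPM, adjusted p = 0.0171) with overlapping groups and Ighd by 0.50 (1.63 ± 0.255 against 0.861 ± 0.155 CPM, adjusted p = 0.0272). The myeloid gene Itgam fell (-0.44; 0.678 ± 0.12 against 1.28 ± 0.0993 CPM, adjusted p = 0.0332), and the red cell gene Hbb-bs, at 5.26 ± 7.21 against 0.0363 ± 0.0314 CPM, did not pass (adjusted p = 0.0989). The immediate early and heat shock list stood at a median of 0.33 (adjusted p = 0.0524, and adjusted p = 0.745 with an estimated correlation), with Hspa1a at 1006 ± 735 against 320.5 ± 236 CPM. KO replicate 4 was the lowest library labelled KO for several genes, with Hspa1a at 97.5 against 791 to 1809 CPM, Igkc at 0.991 against 6.53 to 8.98 and Klf4 at 0.532 against 8.50 to 13.95. Without it and WT replicate 3 together 1161 genes passed (596 up, 565 down). Without WT replicates 1 and 3 in turn 466 and 583 genes passed, and without KO replicates 1 and 2 541 and 536.

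W250S naive CD4 T cells changed many of the genes that changed in the KO-labelled set. The actin genes Nebl and Coro2a rose by 2.06 and 1.97. Ptgir rose by 1.85 ± 0.18 (SE; 17.8 ± 3.57 against 4.30 ± 1.47 CPM, adjusted p = 3.86e-06), the small GTPase gene Rhob by 1.75, Gprasp2 by 1.72, Gpc1 by 1.58 and the cyclophilin gene Ppic by 1.33. Prr13, Hsd17b11, Ncf4, Cd1d1, Ifit1bl1 and Mapk11 fell (-1.28, -1.28, -1.27, -1.18, -1.14 and -0.89). The quiescence factor gene Klf4 rose by 1.23 (5.15 ± 1.84 against 1.74 ± 1.36 CPM, adjusted p = 0.0082) with overlapping groups, while Klf2 (0.16) and Cd44 (0.28) did not pass. The IL-2 receptor chain gene Il2rb rose by 0.67, the lineage regulator Id2 by 0.53, Gpr83 by 0.74, Dapl1 by 0.89, Igfbp4 by 0.56 and the cytokine gene Csf1 by 0.78. Interferon-stimulated genes rose in this set, with Ifi44 up by 0.94, Ifit3 by 0.84, Ifit3b by 0.83 and Mx1 by 0.82. The myeloid marker Cd74, at 1.98 ± 0.816 against 0.581 ± 0.105 CPM, rose by 0.89 in the same libraries (adjusted p = 0.00476). Of 34 list members 13 rose (20 up and 1 down adjusted over the list alone; median 0.36, adjusted p = 1.03e-10, and adjusted p = 0.818 with an estimated correlation). The immediate early genes Fos and Fosb rose by 1.71 and 2.00 in the same libraries, with a list median of 0.44 (2 of 18 up, 5 over the list alone; adjusted p = 0.00218, and adjusted p = 0.818 with an estimated correlation). Activation and memory genes leaned up (2 of 22, 3 over the list alone; adjusted p = 0.0381, and adjusted p = 0.818 with an estimated correlation). In all 516 of 12397 genes passed, 410 up and 106 down (210 and 169 after median-ratio scaling). The count was 209, 204 and 330 without W250S replicates 1, 2 and 3.

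The naive comparisons share no library, so their effects were compared directly. Across 12243 genes tested in both, the log2 fold changes correlated with a Pearson r of 0.709 and a Spearman rho of 0.607 (permutation p = 1e-05 for each, the smallest that 100000 permutations can give; genes are not independent replicates). Of 534 genes up in the KO-labelled set and 403 up in the W250S set, 251 were shared, where independent lists would share 17.6 (Fisher's exact test, p = 7.15e-259). Of 457 and 105 genes down, 85 were shared (Fisher's exact test, p = 1.14e-104), with 0 genes called in opposite directions. Fisher's test also takes the genes as independent, which they are not. Tested directly, 0 of 12230 genes differed between the KO-labelled and the W250S effect by limma, with 623 at an unadjusted p under 0.05 where 612 would be expected. Interferon-stimulated genes as a group passed camera, with a median difference of -0.31, KO-labelled minus W250S (adjusted p = 8.99e-11). That call was not kept with an estimated correlation (adjusted p = 0.644).

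**Figure D4:**
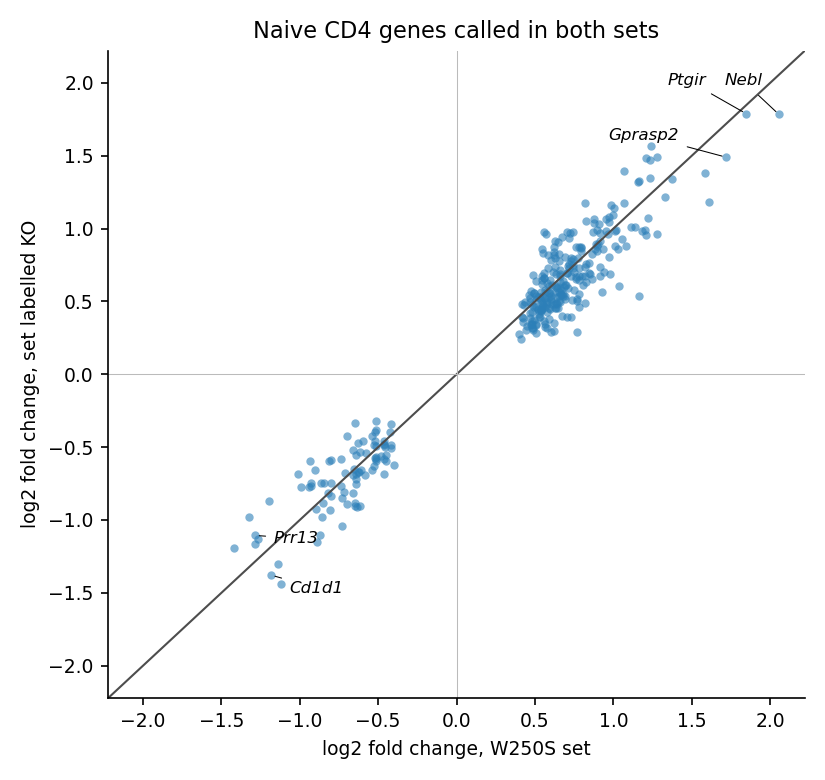
Log2 fold change in the naive CD4 set labelled KO (vertical axis) against that in the W250S set (horizontal axis) for the 336 genes called in the same direction in both; each point is a gene and the line marks equal values. The named genes Ptgir, at 1.85 and 1.79, and Cd1d1, at -1.18 and -1.38, lie near the line.

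Open chromatin in naive CD4 T cells was compared between libraries labelled KO and WT. Of 86911 peaks 47000 were tested by edgeR and 4 passed, 3 with more and 1 with fewer reads in those labelled KO. A peak at the start of Mgll, a gene for a lipase that breaks down monoglycerides (mm10, as the authors' annotation gives it, chromosome 6, 88724222 to 88724922), rose by 1.35 log2 (23.0 against 9.07 normalized CPM). A peak annotated to Dip2c (chromosome 13, 9276290 to 9277455) rose by 1.42, and 1 annotated to the peroxisomal transporter gene Abcd2 (chromosome 15, 91191513 to 91192358) by 1.62. A peak annotated to Tor4a (chromosome 2, 25195314 to 25196892) fell (-0.60), and each of the 4 had an adjusted p of 0.0486. The transcripts moved alike where they were tested, with Dip2c up by 0.70 (adjusted p = 0.0064), Abcd2 up by 1.04 (adjusted p = 0.00076) and Tor4a down (-0.66; adjusted p = 0.00023), while Mgll was too low to test. Of 23 peaks annotated to Elf4, 10 were tested and none passed by edgeR, with log2 fold changes from -1.02 to 0.79 and a lowest adjusted p of 0.349. The most covered, at a start of the gene, held 37.2 against 34.5 CPM and at least 344 reads in each library labelled KO. The stretch changed in the KO allele is not known here, so these peaks cannot decide for or against the label. At an unadjusted p under 0.05 there were 4641 peaks where 2350 would be expected, 2795 of them up. DESeq2 called 64 peaks, 62 up and 2 down, and without WT replicate 1 edgeR called 2070, while without any other library it called 0. Depth went largely with the label. WT replicates 1 and 2 held 6.19 and 6.56 M reads in peaks, fewer than any library labelled KO. WT replicate 3, with 9.71 M, was just above KO replicate 2, with 9.61 M. Whether the lean to peaks with more reads follows depth rather than genotype was not tested.

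Chromatin and RNA changes were related across genes in the libraries labelled KO. Over 8607 genes with a tested peak at the start, log2 fold changes correlated with a Pearson r of 0.224 and a Spearman rho of 0.165 (permutation p = 1e-05 for each, the smallest that 100000 permutations can give; genes are not independent replicates). Of 438 genes whose RNA rose, 297 had a start peak with a positive fold change. Of 362 whose RNA fell, 278 had a negative one (Fisher's exact test over both, p = 1.75e-37). That test also takes the genes as independent, which they are not.

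W250S Th17 cells were compared with WT in each culture, to ask how the substitution acts on effector programs. In pathogenic cultures the memory marker gene Cd44 rose by 0.58 ± 0.069 (SE; 188 ± 15 against 125 ± 7.36 CPM, adjusted p = 0.00264). Single genes of secreted factors rose, the cytokine gene Il1a by 1.15, the growth factor gene Pdgfb by 0.82, Inhba, an activin subunit, by 0.57 and Il13 by 0.72. The stromal marker Lum rose by 0.80 in the same libraries (41.8 ± 4.48 against 23.7 ± 4.66 CPM, adjusted p = 0.00949). Thy1, of the same list, did not pass (167 ± 17.7 against 175 ± 9.94 CPM, adjusted p = 0.67), so Lum alone does not show stromal cells. Cd5l, a regulator of lipid metabolism and Th17 pathogenicity, rose by 1.15, the growth factor receptor gene Egfr by 1.10 and Ppic by 1.33. The calcium-binding gene S100a6 rose by 0.83, the chemokine receptor gene Ccr6 by 0.61, the transcription inhibitor Id3 by 0.56 and Egr1 by 0.39. The signature cytokines were higher without passing, Il17f at 37.7 ± 16.1 against 17.8 ± 6.05 CPM (adjusted p = 0.0693) and Il17a at 4.96 ± 2.99 against 2.36 ± 0.737 CPM (adjusted p = 0.177). Il23r (-0.36) and Csf2 (-0.25) did not pass. Interferon-related genes fell, Trim30a (-1.10), Trim30d (-1.08), Parp14 (-0.93), the signal transducer Stat2 (-0.79) and the double-stranded RNA kinase gene Eif2ak2 (-0.78). Il21 fell (-0.46), the Aiolos gene Ikzf3 (-0.58), the protease gene Ctss (-0.96) and Nrp1 (-0.44).

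In all 263 of 12794 genes passed in pathogenic Th17 cells, 114 up and 149 down. Of 21 interferon-stimulated genes 5 fell (12 adjusted over the list alone; median -0.47, adjusted p = 4.3e-11, and adjusted p = 0.659 with an estimated correlation). Pro-inflammatory cytokines leaned up (2 of 8, 4 over the list alone; adjusted p = 0.0165, and adjusted p = 0.484 with an estimated correlation). The count fell to 92 without WT replicate 1, 63 without W250S replicate 1 and 42 without W250S replicate 3.

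**Figure D5:**
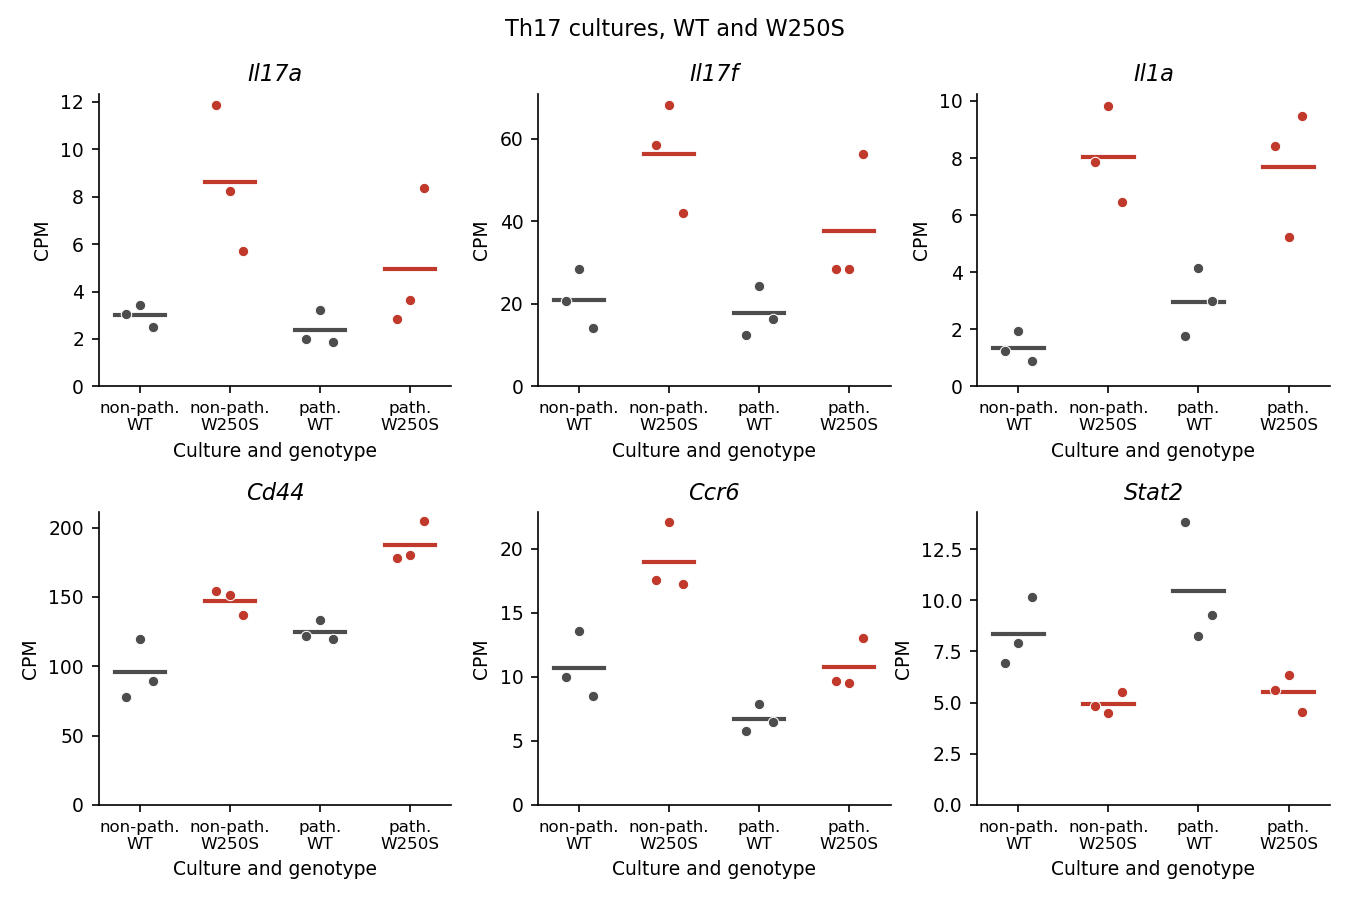
CPM (vertical axes, linear, from 0) of 6 genes in each Th17 library, by culture and genotype (horizontal axes); points are libraries and bars are group means. Il17a averages 8.61 CPM in W250S against 2.99 in WT non-pathogenic cells and 4.96 against 2.36 in pathogenic cells.

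In non-pathogenic cultures the IL-17 genes passed: Il17a rose by 1.22 ± 0.19 (SE; 8.61 ± 3.08 against 2.99 ± 0.472 CPM, adjusted p = 0.00697) and Il17f by 1.40 (56.2 ± 13.3 against 21 ± 7.08 CPM). Il1a rose by 1.95 and the receptor gene Il1r1 by 1.11, as did Ccr6 by 0.79, Il2 by 0.83, Tnf by 0.56 and Inhba by 0.69. Lum rose by 0.88 (9.07 ± 0.804 against 4.49 ± 0.811 CPM, adjusted p = 0.00314), while Thy1, of the same list, was 171 ± 9.13 against 184 ± 10.3 CPM. Cd44 rose by 0.64, Egfr by 1.10, Ppic by 1.29, Cd5l by 1.07, Ptgir by 0.97, Id3 by 0.64 and the naive-state repressor Bach2 by 0.28. Among the genes that fell were several of amino-acid metabolism and stress, not tested as a list. The pseudokinase gene Trib3 fell (-1.52), the asparagine synthetase gene Asns (-1.09), the mitochondrial carboxykinase gene Pck2 (-1.16), Chac1 (-1.07), the transaminase gene Gpt2 (-1.06) and the translation repressor gene Eif4ebp1 (-0.83). The Th1 receptor gene Il12rb2 fell (-0.91), the T cell receptor-induced genes Tnfrsf9 and Nr4a3 (-0.66 and -0.72), Prr13 (-0.90), and the interferon-related Isg15 and Stat2 (-1.0 and -0.64).

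In all 905 of 12821 genes passed in non-pathogenic Th17 cells, 528 up and 377 down (1708 after median-ratio scaling, 797 up and 911 down). Of 15 Th17 core genes 4 rose (6 up and 1 down adjusted over the list alone), though the list did not pass camera (adjusted p = 0.0555). Interferon-stimulated genes fell, 6 of 19 (10 down and 1 up over the list alone; median -0.34, adjusted p = 4.87e-07, and adjusted p = 0.762 with an estimated correlation). Glycolysis genes leaned down, among them Aldoa (-0.21; 2 of 20, 3 over the list alone; adjusted p = 0.000961, and adjusted p = 0.762 with an estimated correlation). The count was 2112 without WT replicate 2, 61 without WT replicate 3, and 89, 54 and 364 without W250S replicates 1, 2 and 3.

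The W250S effect was not shown to differ between the cultures for any single gene: 0 of 12642 genes passed by limma. Here the difference between cultures was taken within each source of cells that the labels name by number. There were 1130 genes at an unadjusted p under 0.05 where 632 would be expected. A fit without this pairing also called 0 genes by limma, with 1195 at an unadjusted p under 0.05. As groups, Th17 core genes (median difference -0.26, pathogenic minus non-pathogenic, adjusted p = 0.00871), quiescence genes (-0.14, adjusted p = 0.0102) and the non-pathogenic Th17 signature (-0.29, adjusted p = 0.0233) leaned lower in the pathogenic culture. Glycolysis genes leaned higher (0.12, adjusted p = 0.0102). With an estimated correlation each of these had an adjusted p of at least 0.722. The labels give each source of cells the same number in both cultures, but once group means were removed, 0 of 3 WT and 1 of 3 W250S libraries correlated best with their own number (-0.04 to 0.15 in WT, -0.21 to 0.12 in W250S). The match of numbers to sources is therefore uncertain. Without pathogenic WT replicate 2, 468 genes passed.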

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

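The block of genotype and replicate number, the tests of library scaling, of dilution by another cell type and of W250S cells under the KO label, the fits without BMDM KO replicate 2 and those with the immediate early and heat shock list as a covariate were chosen only after the result was seen. The other tests here were fixed earlier.

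The KO effect in macrophages differed between 16 h and 0 h of LPS, by a test of the difference itself, for 778 genes. The named differences were Ifit1bl1 -3.36, Gbp4 -3.15, Lipg -3.14, Cxcl11 -3.12 and Iigp1 -2.51 on the negative side, and Pclaf 1.73, Plpp5 1.53, Ccna2 1.44 and Draxin 1.44 on the positive side. Median differences of lists past camera at 16 h were -0.87 for interferon-stimulated genes, -0.78 for other chemokines, -0.57 for pro-inflammatory cytokines, -0.33 for antigen presentation, -0.29 for the inflammasome, -0.275 for dendritic cell markers, -0.24 for inflammation amplifiers, -0.22 for anti-inflammatory regulators, -0.17 for TLR signalling and -0.0765 for immediate early and heat shock genes, against 0.89 for cell cycle, 0.47 for cholesterol synthesis and 0.33 for glycolysis. Of these the other chemokine, cytokine, inflammasome and cholesterol calls held with an estimated correlation; the rest had an adjusted p of at least 0.0708 with it. At 4 h the difference passed for 1 gene, Mtus1 (-1.17). Median differences past camera at 4 h were -0.26 for interferon-stimulated genes, -0.15 for antigen presentation, -0.0771 for TLR signalling and -0.0601 for the inflammasome (adjusted p = 0.0535 with genotype and replicate number as a block), against 0.52 for neutrophil chemoattractants, 0.26 for cholesterol synthesis, 0.24 for cell cycle, 0.22 for immediate early and heat shock genes and 0.17 for glycolysis, each with an adjusted p of at least 0.236 with an estimated correlation. Between Th17 cultures the W250S effect was not shown to differ for any single gene. Median differences past camera (pathogenic minus non-pathogenic) were -0.29 for the non-pathogenic signature and -0.26 for Th17 core genes. Those of quiescence genes and glycolysis were -0.145 and 0.115. Between naive sets (KO-labelled minus W250S) no single gene passed either, and interferon-stimulated genes passed camera with a median of -0.31. All of these lists had an adjusted p of at least 0.644 with an estimated correlation.

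Other splits of the same libraries were fitted in the same way. For the naive cells labelled KO, 1 of 35 splits, the real one, called as many genes (1036 against a highest other of 299). That share is under the line of 0.05 set in advance, but with so few splits and several counts examined it does not exclude chance. For the 3 against 3 comparisons 10 splits are too few for a share under 0.05: real and highest other counts were 53 and 30 for BMDM KO at 0 h, 505 and 0 at 4 h, 3683 and 1 at 16 h, 10469 and 0 for LPS at 4 h, 9021 and 0 for LPS at 16 h, 516 and 1 for naive W250S, 263 and 0 for pathogenic and 905 and 0 for non-pathogenic Th17 cells, and 4 and 0 for ATAC-seq peaks. In these the number of splits calling as many as the real one was 1. For the KO effect at 16 h minus that at 0 h the splits decide nothing about chance. Of 100 splits 8 called as many as 778 (highest other 2523), but each of the 7 others kept the 16 h genotypes and exchanged 0 h libraries, so it held the genotype difference at 16 h itself. Of the splits of that kind 7 of 9 were as large, against 0 of 78 and 0 of 12 of the other kinds. The same holds at 4 h, where 13 of 100 splits called at least the 1 gene (highest other 624), 10 of the 12 others with the 4 h genotypes kept. A count of 0 is met by every split, which says nothing about chance for the difference between the naive effects (100 of 100 splits, highest other 49) or between the Th17 cultures (10 of 10 splits, highest other 0). A split that calls several times the real count, as the highest at 16 h does, follows a structure of the libraries, here the genotype difference at 16 h that it keeps.

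The first pattern weighed is the lower level of interferon-stimulated genes in BMDM KO at 16 h, with a median of -0.65. The camera call on this list was not kept with an estimated correlation. Library scaling is argued against by a median of -0.745 after median-ratio scaling. Dilution of macrophage RNA by another cell type would have lowered macrophage identity genes as well, and their median was 0.118, near the 0.124 of all genes. Some macrophage genes also move with LPS, such as Mrc1, which fell in WT cells and was higher in KO at 16 h. Dilution offset by such moves is therefore not excluded. The KO replicate with the most stroma RNA does not carry it either, since the median was -0.584 without KO replicate 2 at every time. What also stays open is a biological difference of genotype, a hypothesis found and tested on the same data. Any difference between the animals that goes with genotype stays open too, since the design confounds it with genotype.

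The second pattern is that the naive libraries labelled KO shared 336 called genes with W250S while Elf4 stood at the WT level (189 against 191 CPM). Handling before lysis is argued against, since with the immediate early and heat shock list as a covariate the shared genes kept a median of 0.975 of their log2 fold change, and 273 of them were still called in both. An exchange of labels between KO and WT libraries is argued against by 0 libraries in the range of the other group on a score of 508 genes called for W250S. W250S cells under the KO label cannot be told apart from a knockout whose transcript is still made, since the slope of KO-labelled on W250S fold changes was 0.988, a value that both allow. A knockout allele that leaves transcripts at the WT level in T cells but not in macrophages is also open and was not tested.

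The third pattern is the movement of interferon-stimulated genes with W250S, up in naive cells and down in both Th17 cultures. That 1 library sets the group is argued against in each: the median nearest to 0 was 0.26 without W250S replicate 3 in naive cells, -0.31 without WT replicate 1 in pathogenic and -0.19 without WT replicate 3 in non-pathogenic cells, against 0.36, -0.47 and -0.34 with every library. The camera calls were not kept with an estimated correlation (adjusted p = 0.818, 0.659 and 0.762), so the genes may move as 1 unit with the state of a few mice. A genotype effect that depends on cell state and a difference in exposure of the mice to interferon stay open; the difference between naive and Th17 cells was not tested.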

How the results depend on the processing

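The fits without BMDM KO replicate 2, the blocks of genotype and number, the covariate and the fit without naive WT replicate 3 and KO replicate 4 were chosen only after the result was seen. Of 281 values given for named genes, 181 kept their direction and their side of the threshold under every alternative run, those without 1 library included; 85 were no longer past the threshold under at least 1 alternative and 14 newly passed. The value that turned over was Elf4 at 4 h of LPS in WT macrophages, -0.61 as deposited and 0.23 after median-ratio scaling, which by construction removes the shift of all genes (-0.81). For the changed counts below the cause was not tested. With 3 libraries per group, genes whose change is under 1.5-fold are often missed.

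Median-ratio scaling changed the BMDM KO count at 0 h from 53 to 29 and the non-pathogenic Th17 count from 905 to 1708, and moved the balance of up and down at 0 h to 7 and 22 and in pathogenic Th17 cells to 128 and 222. Without a filter on low values naive W250S gave 330 genes in place of 516, and ATAC-seq 52 peaks in place of 4. A fit to the groups compared gave 1 gene at 0 h, 248 at 4 h in place of 505, and 0 in place of 1 for the difference at 4 h. The replicate number as a block gave 103 at 0 h, 4 and 1191 for the differences at 4 h and 16 h, 1597 in place of 1036 for naive cells labelled KO, 1261 for naive W250S, 1469 for non-pathogenic Th17, 3 in place of 0 for the difference between naive effects and 0 for ATAC-seq. The block of genotype and number gave 43 and 1788 for the differences at 4 h and 16 h (1 and 778 without). With it, the list calls that changed in macrophages across time were alternative activation in WT at 16 h (adjusted p = 0.091 in place of 0.0432), stromal markers in WT at 16 h (0.00474 in place of 0.0905), for the difference at 4 h the inflammasome (0.0535 in place of 0.0423) and other chemokines (0.0245 in place of 0.0924), and for that at 16 h the lysosome list (0.0371 in place of 0.0716). Without BMDM KO replicate 2, 20 genes passed at 0 h and 2 for the difference at 4 h. For ATAC-seq, DESeq2 gave 64 peaks and an adjusted p below 0.01 gave 0. With an estimated correlation 23 of 216 list tests passed, in place of 92; 93 passed with median-ratio scaling, 89 of them in both, and 77 with fry.

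Leaving out 1 library at a time, counts ranged from 18 (without WT replicate 2) to 95 (without KO replicate 3) for BMDM KO at 0 h and from 247 (without WT replicate 3) to 473 at 4 h. They ranged from 2515 to 3501 at 16 h, from 10186 to 10279 for LPS at 4 h, from 8539 to 8635 for LPS at 16 h, from 0 to 40 (without KO 4 h replicate 1) for the difference at 4 h and from 282 (without WT 0 h replicate 2) to 1031 for that at 16 h. In T cells they ranged from 466 (without WT replicate 1) to 1380 for naive cells labelled KO (1161 without WT replicate 3 and KO replicate 4 together), from 204 (without W250S replicate 2) to 557 for naive W250S, from 42 (without W250S replicate 3) to 370 for pathogenic and from 54 (without W250S replicate 2) to 2112 (without WT replicate 2) for non-pathogenic Th17. The difference between Th17 cultures gave 0 to 468 (without pathogenic WT replicate 2), and ATAC-seq 0 to 2070 (without WT replicate 1). The correlations across genes ranged from 0.159 to 0.248 for ATAC-seq with RNA and from 0.658 to 0.713 between the naive effects.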

Other observations

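No test given here was chosen only after the result was seen. In macrophages the calprotectin partners S100a8 and S100a9 were far apart in level: at 16 h S100a9 was 3.52 ± 3.25 against 1.01 ± 0.324 CPM in KO against WT (adjusted p = 0.201), where S100a8 was 80.1 ± 16 against 30.1 ± 6.06 CPM and rose. The cathepsin gene Ctsb, an abundant lysosomal protease, was 6953 ± 760.4 against 8195 ± 494 CPM (adjusted p = 0.162), and Ccl5, an abundant chemokine of the later response, 3209 ± 608 against 3814 ± 245 CPM (adjusted p = 0.535). On log2(CPM + 1), log2 differences of at least 1 either way made up 284 of 3683 calls for BMDM KO at 16 h, 134 up and 150 down. They made up 29 of 505 at 4 h and 14 of 53 at 0 h, and 188 of 778 for the difference between 16 h and 0 h. In WT cells they made up 6108 of 10469 calls for LPS at 4 h and 3777 of 9021 at 16 h.

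In W250S Th17 cells, regulators of other T helper fates did not pass. Tbx21, which directs Th1 cells, was 15.7 ± 3.31 against 15 ± 0.85 CPM in pathogenic (adjusted p = 0.889) and 21.4 ± 1.92 against 18.1 ± 2.20 CPM in non-pathogenic cells (adjusted p = 0.139). Foxp3, which directs regulatory T cells, was 1.30 ± 0.131 against 1.18 ± 0.361 CPM (adjusted p = 0.776) and 1.34 ± 0.302 against 1.5 ± 0.343 CPM (adjusted p = 0.712), and the IL-2 receptor gene Il2ra 717 ± 55.7 against 795 ± 18 CPM (adjusted p = 0.222) and 749 ± 41.5 against 779 ± 98.6 CPM (adjusted p = 0.727). Log2 differences of at least 1 either way, on log2(CPM + 1), made up 8 of 263 calls in pathogenic and 14 of 905 in non-pathogenic cells. They made up 46 of 1036 in naive cells labelled KO and 50 of 516 in naive W250S cells. These counts miss genes of low level, whose change the added 1 shrinks. Il13 in pathogenic cells, at 1.37 against 0.437 CPM, stood at 0.72.

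Counts of genes whose groups did not overlap were 1715 at 0 h, 2696 at 4 h and 5868 at 16 h of 12058 for BMDM KO, 2692 of 12397 for naive W250S, 3126 of 12794 for pathogenic and 4056 of 12821 for non-pathogenic Th17 cells, where chance gives 10%, and 2741 of 12904 for naive cells labelled KO, where chance gives 5.71%. For ATAC-seq 7024 of 47000 peaks had groups that did not overlap, 14.9%, where chance gives 10%.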
